A study of Mus musculus with 7 samples.

How the data were processed

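RNA was measured in 7 libraries from fetal liver cells of C57BL/6 mice at 13.5 days post coitum. There were 3 libraries each of wild-type and Uhrf1-/- LSK cells and 1 library of wild-type LK cells. Per the labels' protocols, the cells were sorted in 2 rounds, RNA integrity was checked, and libraries were made with the TruSeq RNA kit and sequenced on an Illumina instrument. Groups and replicate numbers were taken from the sample titles. The series design speaks of 3 independent experiments, and nothing in the sources used here says which animals or litters went into each library.

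The deposited table has 22680 genes with 2 values per library. The first is deposited as a count per the file headers, but the values are not whole and were used as a scaled count signal. What the authors did to make them is not given in the sources used here. Between 98.2% and 98.6% of its values above 0 and below 100 steps lie within 0.02 steps of a whole multiple of the library's step, and the rest are fractional, so a count model was not run. The design fixed beforehand named FPKM or whole counts, and its FPKM branch was followed. The second value is FPKM, read fragments scaled by gene length and library size, as deposited by the authors. TopHat2 2.0.9, Cufflinks 2.1.1 and the mm10 build are named per the submitters' processing notes, without roles. The annotation, the strand setting and the counting options are not given in the sources used here, so reads of overlapping genes and of near-identical copies cannot be told apart. The ratio of FPKM to scaled count of a gene differs between libraries, so the 2 measures are not related by a single length per gene. FPKM is a share, and a library in which a few genes take many reads has lower values elsewhere. The table gives Entrez gene IDs, of which 373 rows have none, and 27 symbols look like dates and were not named. Coordinates come from a RefSeq annotation of GRCm38, the assembly called mm10 in the notes, matched by gene ID for 22235 rows.

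The scaled counts summed to 15556959 to 21017402 per library, and dividing by the step gave estimated read totals of 16808525 to 25803048. An exact 0 is described as listed at 0. The most similar libraries, Uhrf1-/- replicates 1 and 2 (r = 0.994 on the log2 scale), differed by a median chi-square of 3.34 per gene with at least 20 estimated reads. Sampling noise gives 0.455, so no library was a copy of another and all were counted separately. Wild-type LSK libraries differed from each other by 20.96 to 32.77, and Uhrf1-/- replicate 3 from replicates 1 and 2 by 19.43 and 21.90. These values do not show that the libraries came from separate animals or sorts.

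Genotypes were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) over the 6 LSK libraries, with empirical Bayes moderation (trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean of at least 1 FPKM over these libraries were tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The replicate number was checked as a pairing. The deviations from the group means correlated at 0.349, 0.332 and 0.645 for libraries of the same number, and each library correlated best with its own number (other numbers between -0.591 and 0.213). All 3 were above 0.1, so the numbers were read as pairing the libraries. Wild-type replicate 2 with Uhrf1-/- replicate 1 (0.213) and wild-type replicate 1 with Uhrf1-/- replicate 2 (0.159) were also above 0.1. The limit thus sets replicate 3 apart but cannot tell pairs 1 and 2 from each other. Deviations within a group cancel out, so the offset of replicate 3 alone can raise the values of pairs 1 and 2. On the log2 values themselves, Uhrf1-/- replicate 2 correlated more with wild-type replicate 1 (r = 0.9821) than with wild-type replicate 2 (0.9505). Uhrf1-/- replicates 1 and 3 correlated best with the wild-type library of their own number (0.9835 and 0.9644). The blocked fit rests on reading the numbers as pairs. This reading comes from the data, since the labels do not say what a number shares. Adjusted p-values are from the fit without the block unless a blocked value is named. P-values measure the spread between these libraries, and with the block the spread left after the pairs are removed. The moderation draws each gene's spread toward that of genes of like level. With so few libraries much of the spread behind a p-value is thus borrowed from other genes.

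There were 20 gene lists with 482 entries, fixed before the data were examined: DNA methylation genes, methylation-silenced germline genes, imprinted genes, interferon-stimulated genes, stem cell regulators and markers, erythroid, megakaryocyte, myeloid, lymphoid, and mast cell, basophil and eosinophil genes, DNA replication, mitosis, p53 targets and CDK inhibitors, cell polarity, immediate-early and heat-shock genes, Y-linked genes with Xist, and markers of hepatoblasts, macrophages, endothelium and stroma. Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. The rule for named genes, also fixed beforehand, was Uhrf1, the 10 highest and 10 lowest genes past the threshold with non-overlapping ranges (filled by smallest unadjusted p and named as not passing), up to 4 members per list with the smallest adjusted p, and the 10 highest and 10 lowest LK differences outside the wild-type LSK range with at least 5 FPKM in the higher group. Genes that passed only with the block were named by list as called, which adds some outside that rule, and Hba-a1 in the knockout, Junb, Flt3, Isg15 and Rhd were chosen after their values were seen.

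The LK library was compared as a value against the mean, SD and range of the wild-type LSK libraries, over genes with a mean of at least 1 FPKM over the 2 groups. A limma fit over all 7 libraries in 3 groups, which assumes that LK libraries would vary like LSK libraries, was added. The median of each list in the LK comparison was ranked among 10000 random lists matched in 20 bins of expression. The correlation of the knockout effect with the LK difference was set beside 200 simulations of unchanged groups that share the wild-type LSK libraries. The overlap of calls was set beside 20 such simulations, in which the genes with the smallest p in each direction made lists of the real sizes, a comparison chosen after the overlap was seen.

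The limma and camera code was tested on simulated data for the genotype comparison over 10608 genes, with 200 changed genes in each of 10 simulations. The fit without the block recovered 4.60% of genes changed by 1 on the log2 scale and 80.1% of those changed by 2, and 0.703% of its calls were false. With the block it recovered 67.7% and 98.6%, and 9.31% of its calls were false, more than the 5% that the threshold allows on average. These simulations gave libraries of the same number a shared spread, took the remaining spread from the blocked fit and treated genes as independent. The blocked figures thus assume that the pairing is real. Fits without a pair were not simulated. Alternatives tried were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, the replicate block, leaving out each library, plain empirical Bayes and an estimated correlation in camera. Chosen after seeing the data were the scaled counts with and without the block, the block without each pair, the block with median-of-ratios scaling, and a correlation with no shared library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.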

Results

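Gene expression was measured by RNA sequencing in blood-forming cells sorted from the livers of C57BL/6 mouse fetuses at 13.5 days post coitum, the stage at which the fetal liver is the main site of blood formation. The deleted gene, Uhrf1, encodes a protein that binds hemimethylated DNA and brings the maintenance DNA methyltransferase Dnmt1 to replicating DNA. LSK cells lack lineage markers and carry Sca-1 and c-Kit, and this fraction holds the hematopoietic stem cells and multipotent progenitors. LK cells carry c-Kit without Sca-1 and hold progenitors that are further along in differentiation. There were 3 libraries of wild-type LSK cells, 3 libraries of Uhrf1-/- LSK cells and 1 library of wild-type LK cells. Per the series design, LSK cells were sorted in 3 independent experiments. The deposited count values summed to between 15556959 and 21017402 per library, and the read totals estimated from their step lay between 16808525 and 25803048.

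Replicate 3 differed from replicates 1 and 2 in both genotypes in immediate-early genes. Among these, Junb, which responds within minutes to stimulation and handling of cells, stood at 198 and 188 FPKM in wild-type replicates 1 and 2 and at 250 and 215 FPKM in Uhrf1-/- replicates 1 and 2. In replicate 3 it stood at 5.31 FPKM in wild-type and 22.4 FPKM in Uhrf1-/- cells, and the LK library had 8.09 FPKM. Ribosomal protein genes took 4.49% of the count values in wild-type LSK replicate 2 and between 10.1% and 14.9% in the other 6 libraries. The first principal component, with 47.2% of the variance, separated the LK library from the LSK libraries and replicate 3 from replicates 1 and 2. The second component, with 24.5%, was set mainly by wild-type replicate 2 and Uhrf1-/- replicate 3.

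**Figure D1:**
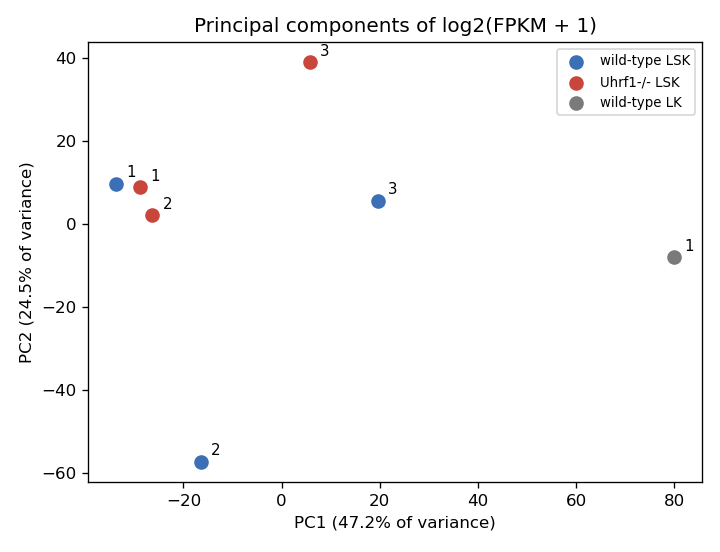
Principal components of log2(FPKM + 1) over the genes tested between genotypes, with PC1 (47.2% of the variance) on the x axis and PC2 (24.5%) on the y axis; each point is 1 library, coloured by group and numbered by replicate. Wild-type replicate 1 and Uhrf1-/- replicates 1 and 2 lie close together, and the LK library lies apart at 79.99 on PC1.

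Uhrf1 (Entrez gene 18140; chromosome 17, positions 56303337 to 56323486 of GRCm38, a protein-coding gene) was measured first, as the gene that the genotype labels name. Its level was 63.0, 66.8 and 112.8 FPKM in the wild-type LSK libraries, 10.2, 8.78 and 18.6 FPKM in the Uhrf1-/- LSK libraries and 115.9 FPKM in the LK library. The mean fell from 80.9 ± 27.7 (SD, n = 3) to 12.5 ± 5.29 FPKM (SD, n = 3). The log2 fold change was -2.62 (SE 0.34), lower in 3 of 3 pairs, with a limma adjusted p of 0.018. The level of the deleted gene went with the genotype label in every LSK library. Which part of the gene was deleted is not given in the sources used here. The adjusted p did not pass when any 1 wild-type library (0.065 to 0.109) or Uhrf1-/- replicate 2 (0.061) was left out.

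The comparison of Uhrf1-/- with wild-type LSK cells addressed how loss of Uhrf1 changes the transcriptome of fetal liver stem and progenitor cells. Single erythroid, megakaryocyte and mast cell genes were among those that rose in Uhrf1-/- LSK cells, and lymphoid and myeloid receptor genes were among those that fell. Gata1 (Entrez gene 14460; chromosome X, 7959260 to 7976663), a transcription factor required for red cell and platelet formation, rose from 6.43 ± 3.80 to 59.4 ± 7.78 FPKM (SD, n = 3 each; log2 fold change 3.19, SE 0.42, adjusted p = 0.021). Zbp1 (Entrez gene 58203; chromosome 2, 173206612 to 173218959), an interferon-inducible nucleic acid sensor, rose from 1.46 ± 0.737 to 17.7 ± 4.28 FPKM (log2 fold change 2.94, SE 0.31, adjusted p = 0.015). Cpa3 (Entrez gene 12873; chromosome 3, 20215616 to 20242209), a mast cell carboxypeptidase, rose from 5.84 ± 3.42 to 46.5 ± 7.69 FPKM (log2 fold change 2.89, SE 0.34, adjusted p = 0.018). The apolipoprotein gene Apoc1 rose from 33.5 ± 18.4 to 181.1 ± 4.50 FPKM (log2 fold change 2.57, adjusted p = 0.038). Further genes that rose were Mfsd2b, which encodes a sphingosine-1-phosphate transporter of red cells and platelets, Car1, Treml1, Cdc42ep5 and Tmem40, with log2 fold changes from 1.86 to 2.12. Sva was listed at 0 in all 3 wild-type LSK libraries and in the LK library, and at 3.31, 2.87 and 2.27 FPKM in the Uhrf1-/- libraries.

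Among the genes that fell, Ccr9 (Entrez gene 12769; chromosome 9, 123767211 to 123783457), a chemokine receptor of thymus-seeding progenitors, went from 5.51 ± 0.477 to 0.775 ± 0.518 FPKM (SD, n = 3 each; log2 fold change -1.92, SE 0.28, adjusted p = 0.030). Csf1r (Entrez gene 12978; chromosome 18, 61105572 to 61131139), the receptor for macrophage colony-stimulating factor, went from 11.2 ± 2.47 to 2.81 ± 0.449 FPKM (log2 fold change -1.67, SE 0.27, adjusted p = 0.043). Lax1 (Entrez gene 240754; chromosome 1, 133679017 to 133693022), an adaptor of lymphocyte receptor signalling, went from 19.99 ± 3.44 to 5.58 ± 0.388 FPKM (log2 fold change -1.66, SE 0.25, adjusted p = 0.035). Slc26a11 and Stc1 also fell, with log2 fold changes of -1.59 and -1.58. The next lowest genes by unadjusted p were Pirb, Rasgrp3, H2-Oa and Pld4, with log2 fold changes between -2.18 and -1.25. These 4 did not pass without the replicate block (adjusted p from 0.054 to 0.104) and passed with it (adjusted p from 0.00019 to 0.0042).

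Over the 10608 genes tested with limma, 12 were higher and 6 lower in Uhrf1-/- cells at an adjusted p under 0.05, and with the replicate number as a block 131 were higher and 88 lower. All 18 genes were also called in the blocked fit, whose fold changes equal those without the block, so their direction could not differ. Of the tested genes, 1142 (10.8%) had ranges that did not overlap between genotypes, where chance gives 10% for 3 against 3 libraries. Leaving out any 1 of the 6 libraries lowered the unblocked count to between 0 and 4 genes, with 0 in the limma fit without wild-type replicate 1 or 2, where 1499 and 466 genes had an unadjusted p under 0.05. Without pair 2, which holds the wild-type library with the low ribosomal protein share, the blocked fit called 13 genes higher and 8 lower, and without pair 1 it called 338 and 318. The fits without a pair leave very few libraries to estimate the spread, and their share of false calls was not simulated. Passing or failing in them, here and below, thus does not settle a single gene.

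**Figure D2:**
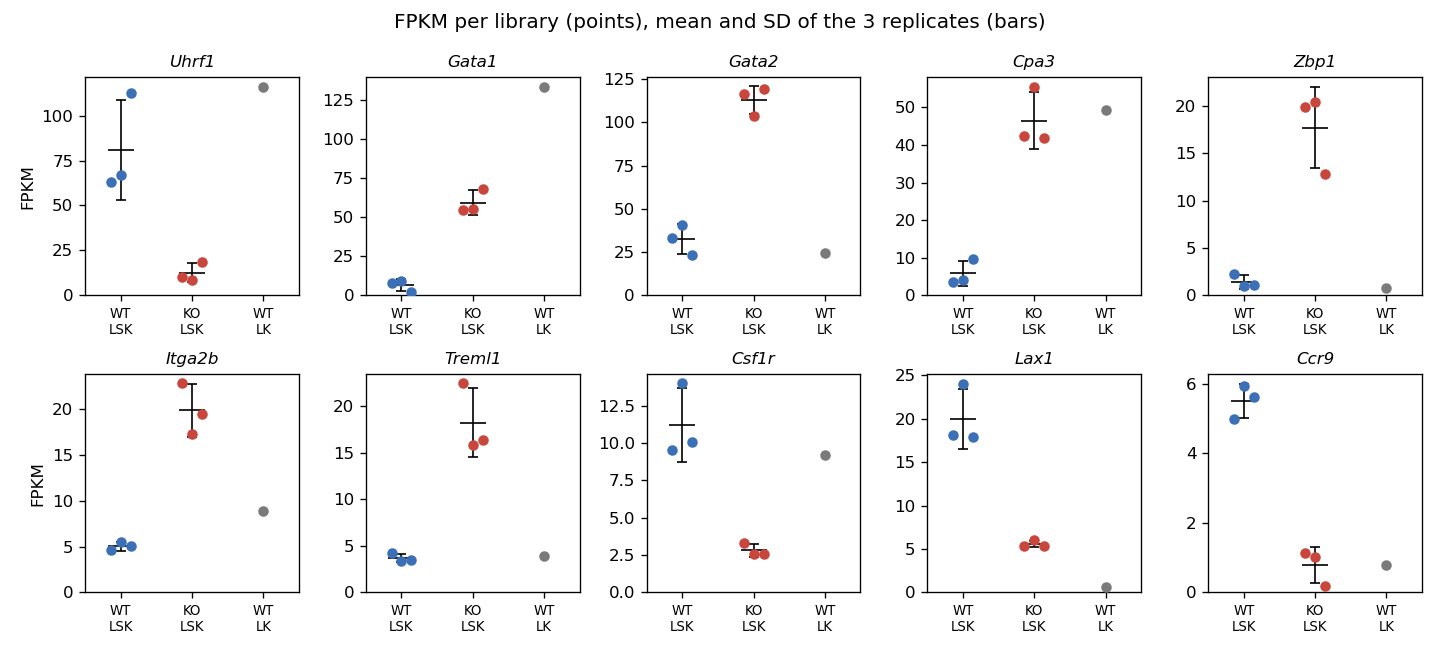
FPKM (y axis, starting at 0) of Uhrf1 and 9 other genes in each library; blue points are wild-type LSK, red points Uhrf1-/- LSK and the grey point the wild-type LK library, and the bars give the mean and SD of the 3 replicates. Uhrf1, Csf1r, Lax1 and Ccr9 lie lower in all 3 Uhrf1-/- libraries than in any wild-type LSK library, and the other 6 genes lie higher.

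Interferon-stimulated genes, which cells switch on in response to type I interferon, were higher as a group in Uhrf1-/- LSK cells. Of 31 tested members, 30 had a positive log2 fold change, with a median of 1.14. Zbp1 was called among all genes, 21 members were higher when adjusted over the list alone, and 13 were called among all genes with the replicate block. Isg15, a ubiquitin-like protein, was 34.6 ± 12.8 FPKM in wild-type and 148.1 ± 56.8 FPKM in Uhrf1-/- cells (SD, n = 3 each; adjusted p = 0.089, blocked adjusted p = 0.011). Irf7, a transcription factor of the interferon response, was 17.0 ± 0.749 and 56.5 ± 14.3 FPKM (adjusted p = 0.053, blocked adjusted p = 0.00057). The antiviral genes Oas3 and Mx1 had log2 fold changes of 1.55 and 1.29 and blocked adjusted p-values of 0.0009 and 0.0033. The list was higher by camera with a preset correlation (adjusted p = 1.95e-30). With an estimated correlation the camera call was lost (adjusted p = 0.060, blocked adjusted p = 0.414). The median difference was 1.03, 1.18 and 0.79 in replicate pairs 1, 2 and 3. Without pair 2 the blocked fit called 1 of the 31 members, and 20 had an unadjusted p under 0.05. The macrophage markers C1qa, C1qb and C1qc summed to 146.5, 70.1 and 1.12 FPKM in wild-type replicates 1, 2 and 3 and to 33.5, 35.4 and 2.12 FPKM in the Uhrf1-/- replicates.

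Erythroid genes were split. Of 24 tested members, Gata1 and Car1, a red cell carbonic anhydrase, were called higher, 9 were higher when adjusted over the list alone, and with the replicate block 8 were higher and Rhd, a red cell membrane protein gene, was lower. Rhd was 3.54 ± 2.26 FPKM in wild-type cells (SD, n = 3) and stood at 1.47, 0.815 and 0.721 FPKM in the Uhrf1-/- libraries, and no erythroid gene was called lower in the blocked fit on the count values or after median-of-ratios scaling. Car1 rose from 1.66 ± 0.785 to 9.74 ± 0.999 FPKM, while the LK library had 69.9 FPKM. Icam4 and Gfi1b, a transcriptional repressor of the erythroid and megakaryocyte lineages, rose in the blocked fit with log2 fold changes of 1.49 and 1.21 (blocked adjusted p = 0.0033 and 0.010). The median log2 fold change of the list was 0.84 (camera adjusted p = 2.70e-07). With an estimated correlation the camera call was lost (adjusted p = 0.448, blocked adjusted p = 0.675). The alpha-globin gene Hba-a1 was 29.8 ± 43.0 FPKM in wild-type and stood at 4.24, 28.9 and 11.3 FPKM in the Uhrf1-/- libraries.

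Of 11 tested megakaryocyte genes, Treml1 and Itga2b were called higher, 4 were higher when adjusted over the list alone, and with the replicate block Gp5 and Gp9, platelet glycoprotein genes, joined them. Itga2b, which encodes the integrin CD41, rose from 5.04 ± 0.469 to 19.9 ± 2.85 FPKM (SD, n = 3 each; log2 fold change 1.78, adjusted p = 0.027), and the LK library had 8.90 FPKM. Treml1 rose from 3.69 ± 0.433 to 18.2 ± 3.70 FPKM (log2 fold change 2.02, adjusted p = 0.018), and the LK library had 3.93 FPKM. The list median was 1.07 (camera adjusted p = 5.44e-07). With an estimated correlation the camera call was lost (adjusted p = 0.066, blocked adjusted p = 0.414). Of 5 tested mast cell, basophil and eosinophil genes, Cpa3 was called higher, 2 were higher when adjusted over the list alone, and the eosinophil ribonuclease gene Ear2 rose with the block (0.188 ± 0.166 against 2.19 ± 1.49 FPKM, blocked adjusted p = 0.016), a member of a family of near-identical genes whose reads the counting can divide in ways not known here. The median of this list was 0.89 (camera adjusted p = 7.29e-05), and its call was also lost with an estimated correlation (camera adjusted p = 0.066, blocked adjusted p = 0.414). Ear2 and Gp9 did not pass the blocked fit on the count values (adjusted p = 0.186 and 0.069) or without pair 2, and Gp9 did not pass without pair 3. Without pair 2 the blocked fit called 2 erythroid genes, 3 megakaryocyte genes and 1 gene of the mast cell list higher, and without pair 1 or 3 it called 13 and 4 erythroid genes higher.

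Lymphoid genes were lower as a group in Uhrf1-/- LSK cells. Of 15 tested members, 13 had a negative log2 fold change, with a median of -1.04. Ccr9 and Lax1 were called among all genes, 9 members were lower when adjusted over the list alone, and 8 were called with the replicate block. Flt3, the cytokine receptor of lymphoid-primed progenitors, was 73.8 ± 26.3 FPKM in wild-type and 22.6 ± 10.4 FPKM in Uhrf1-/- cells (SD, n = 3 each; log2 fold change -1.73, adjusted p = 0.176, blocked adjusted p = 0.00044). Il7r, the interleukin-7 receptor, was 2.76 ± 1.62 and 0.240 ± 0.156 FPKM (blocked adjusted p = 0.0046), and Ccr7 was 6.45 ± 2.84 and 0.847 ± 0.734 FPKM (blocked adjusted p = 4.86e-05). The list was lower by camera (adjusted p = 5.38e-11). With an estimated correlation the camera call was lost (adjusted p = 0.060, blocked adjusted p = 0.414). Of 21 tested myeloid genes, Csf1r was called lower, 2 were higher and 2 lower when adjusted over the list alone, and with the replicate block the granule protease gene Ctsg and the granulocyte transcription factor gene Cebpe were higher and Csf1r and S100a8 lower. S100a8 stood at 68.0, 17.9 and 13.1 FPKM in wild-type and at 3.18, 5.22 and 1.11 FPKM in Uhrf1-/- cells. The myeloid list had a median of -0.22 and did not pass (camera adjusted p = 0.365). Without pair 2 the blocked fit called 2 lymphoid genes and 1 myeloid gene lower and no myeloid gene higher, and without pair 1 or 3 it called 4 and 6 myeloid genes lower. On the count values the blocked fit called 0 myeloid genes higher, with 10 myeloid genes at an unadjusted limma p under 0.05 in either direction, and Cebpe also did not pass without pair 3. The C1q genes, which macrophages express, were lower in Uhrf1-/- cells in pairs 1 and 2 and near 0 in both libraries of pair 3.

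Among 34 tested stem cell regulators and surface markers, Gata2, a transcription factor of stem cells and of early erythroid, megakaryocyte and mast cells, rose from 32.6 ± 8.74 to 112.9 ± 8.31 FPKM (SD, n = 3 each; log2 fold change 1.79, SE 0.28, adjusted p = 0.039). The count adjusted over the list alone was 2 higher and 0 lower. With the replicate block Slamf1, which encodes the stem cell surface marker CD150, was also higher (0.866 ± 0.311 against 4.24 ± 0.845 FPKM, blocked adjusted p = 0.0009) and the homeobox gene Hoxa9 lower (34.2 ± 14.6 against 14.7 ± 3.72 FPKM, blocked adjusted p = 0.016). Hlf was 17.5 ± 3.21 and 9.42 ± 0.669 FPKM and passed in neither fit (adjusted p = 0.441, blocked adjusted p = 0.099). Without pair 2 the blocked fit called 1 gene of this list higher and 0 lower, and without pair 3 it called 2 higher and 0 lower, each with 7 at an unadjusted limma p under 0.05. Hoxa9 thus did not pass without either pair, nor Slamf1 without pair 2. The list as a whole had a median of -0.13 and did not pass (camera adjusted p = 0.970).

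Besides Uhrf1 itself, 0 of the 15 tested DNA methylation genes passed in either fit, whether over all genes or adjusted over the list alone, and 0 of these others had an unadjusted limma p under 0.05. Mbd3 stood at 242.9 ± 86.8 FPKM in wild-type and 351.3 ± 47.8 FPKM in Uhrf1-/- cells and Tdg at 7.89 ± 3.34 and 11.5 ± 1.53 FPKM (SD, n = 3 each; adjusted p = 0.942 for each). Of 32 germline genes known to be silenced by promoter methylation, only 6 reached the expression minimum. With the replicate block the X-linked homeobox gene Rhox5 was higher (1.18 ± 1.34 against 6.89 ± 2.54 FPKM, blocked adjusted p = 0.00012) and Ddx4 lower (7.96 ± 4.30 against 2.53 ± 0.555 FPKM, blocked adjusted p = 0.0086), and these were also the 1 higher and 1 lower gene when adjusted over the list alone. Of 19 tested imprinted genes, Phlda2 was higher with the block (2.28 ± 1.18 against 8.41 ± 2.94 FPKM, blocked adjusted p = 0.0023) and was the 1 member called when adjusted over the list alone. Without pair 2 the blocked limma fit called 0 germline and 0 imprinted genes, with 2 of each at an unadjusted p under 0.05. The camera adjusted p was 0.952 for the DNA methylation list, 0.970 for the germline list and 0.365 for the imprinted list. With no filter on low values 23 germline genes were tested and that list turned to higher in Uhrf1-/- cells (camera adjusted p = 0.017), with 0 single genes called by limma and 5 at an unadjusted p under 0.05. Phlda2 did not pass the blocked fit on the count values (adjusted p = 0.316).

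The cell division lists did not pass. Of 32 DNA replication genes, 0 passed in either limma fit and 0 had an unadjusted p under 0.05, with a median log2 fold change of 0.04 (camera adjusted p = 0.672). Of 28 mitosis genes, 0 passed and 1 had an unadjusted p under 0.05, with a median of -0.18 (camera adjusted p = 0.142). Cdkn1a, the p53 target and cell cycle inhibitor p21, was 5.08 ± 2.49 FPKM in wild-type and 10.2 ± 4.11 FPKM in Uhrf1-/- cells (SD, n = 3 each; adjusted p = 0.885, blocked adjusted p = 0.055). Of the 17 tested p53 targets and CDK inhibitors, Perp passed with the block (blocked adjusted p = 0.028) but not without pair 1 or 2 or on the count values, 0 passed without it and 3 had an unadjusted p under 0.05. Of 22 cell polarity and spindle orientation genes and of 22 immediate-early and heat-shock genes, 0 passed in either fit and 0 had an unadjusted p under 0.05 without the block. The camera adjusted p of these 3 lists was 0.672, 0.672 and 0.952. Markers of other cells of the fetal liver passed in neither fit over all libraries, but without pair 3 the blocked fit called 3 of 5 macrophage markers lower in Uhrf1-/- cells, and without pair 1 or 3 it called 1 of 3 stromal markers lower. Without pair 1 it also called 2 mitosis genes and 1 polarity gene lower, 1 p53 target or CDK inhibitor higher and 1 lower, and 2 immediate-early or heat-shock genes higher and 1 lower. Without pair 3 it called 1 immediate-early or heat-shock gene lower. These added calls come from fits whose share of false calls is not known. Of 5 hepatoblast, 5 macrophage, 10 endothelial and 3 stromal markers tested, 0 were called, and 0, 0, 0 and 2 had an unadjusted p under 0.05. Their camera adjusted p-values were 0.762, 0.952, 0.952 and 0.985. Of the 3 tested genes of the list of Y-linked genes and Xist, 0 were called by limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.985). Over the cell division, p53, polarity, immediate-early, other-cell and Y-linked lists, the members that passed without the block when adjusted over the list alone were the stromal markers Sparc, higher, and Postn, lower (unadjusted p = 0.032 and 0.022).

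**Figure D3:**
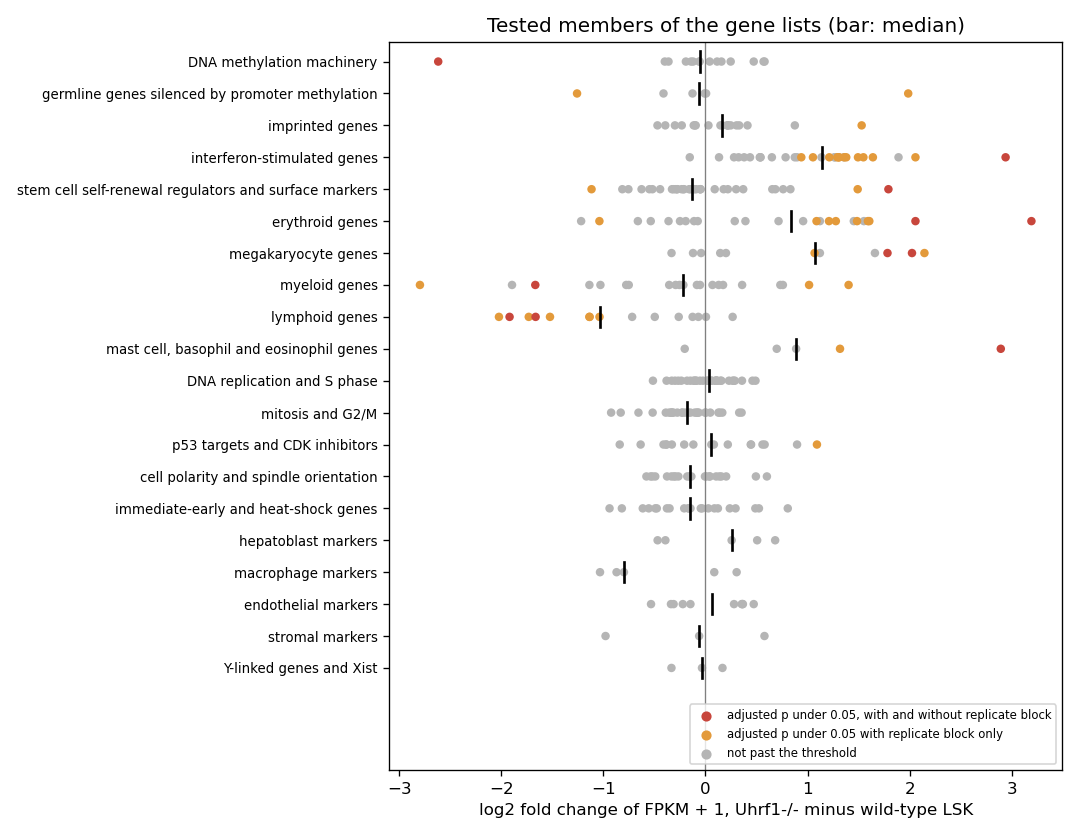
Log2 fold change of FPKM + 1 between Uhrf1-/- and wild-type LSK cells (x axis) for every tested member of the 20 gene lists (y axis); points are genes, red where the adjusted p was under 0.05 in both fits, orange where it was so only with the replicate block and grey otherwise, and the black bar is the list median. The interferon list has a median of 1.14 and the lymphoid list one of -1.04.

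The LK library was compared with the 3 wild-type LSK libraries, which sets progenitors without Sca-1 against the stem cell fraction. Red cell genes dominated the upper end. Hba-a1 stood at 662.8 FPKM in LK cells against 29.8 ± 43.0 FPKM (SD, n = 3) in LSK cells, Hbb-bs at 231.8 against 9.30 ± 9.29 FPKM, and Rhd at 115.3 against 3.54 ± 2.26 FPKM. Cldn13, Ermap, Atp1b2, Car1, Rhag, Tspo2 and the metallothionein gene Mt2 completed the 10 highest differences, from 4.66 to 5.22 on the log2 scale. Hba-a1, Hbb-bs and Mt2 did not pass the pooled limma fit (adjusted p from 0.110 to 0.170). Of 35 erythroid genes, 33 were higher in LK cells, and 22 passed a limma fit that assumes the lone LK library varies like the other groups. The median of that list was 2.88, above all of 10000 random lists of like expression (percentile 100). Myeloid and mast cell genes had medians of 1.07 and 1.66, and of 0.57 and 2.22 against wild-type replicate 3 alone.

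Of the 10 lowest genes, the lymphotoxin gene Ltb was 0.398 FPKM in LK cells against 156.4 ± 125.3 FPKM in LSK cells, Sox18 0.471 against 35.3 ± 18.1 FPKM, and Ccl4 2.89 against 145.4 ± 120.4 FPKM. Ly6a, which encodes Sca-1 and so was set by the sort, was 0.321 against 39.2 ± 15.8 FPKM. The histone gene Hist1h2ap, one of a family of near-identical copies, was listed at 0 in LK cells and ranged from 1417 to 27040.4 FPKM in LSK cells. Klf2, Fos and Jund were also among the 10 lowest, with log2 differences of -4.74, -4.61 and -4.37, and differed from wild-type replicate 3 alone by -0.55, -0.36 and -1.15. H1fx and AI848285 completed the list at -4.37 and -4.28, and at -1.55 and -2.61 against replicate 3 alone. Of these 10 genes, Hist1h2ap, Ly6a and Sox18 passed the pooled limma fit and the other 7 did not (adjusted p from 0.053 to 0.478). Stem cell genes had a median of -1.12 with 28 of 33 lower, lymphoid genes a median of -1.48 with 13 of 16 lower, and interferon-stimulated genes a median of -1.12 with 25 of 26 lower. Endothelial markers had a median of -2.30 and immediate-early genes one of -2.52, which was -0.49 against replicate 3 alone. Over 10646 genes, 182 lay above and 303 below the wild-type LSK range by at least 2 on the log2 scale, and the pooled limma fit called 250 higher and 399 lower. With 1 LK library these differences have no replicate check, and without wild-type LSK replicate 3 the pooled counts were 425 and 610.

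The effect of the knockout in LSK cells was set against the LK difference gene by gene, to see whether Uhrf1-/- LSK cells moved toward the expression of LK cells. Gata1, Car1 and Cpa3 were higher in both, and Lax1, Ccr9 and Flt3 lower in both, while Isg15 and Irf7 were higher in Uhrf1-/- cells and lower in LK cells. Among the blocked calls over the 10320 genes tested in both comparisons, 23 genes were higher in both, where independent lists give 1.65. Another 39 were lower in both, where they give 3.39. Another 10 genes were higher in Uhrf1-/- and lower in LK cells (4.44 for independent lists), and 2 the reverse (1.26). Across the 10608 tested genes, which are not independent replicates, the correlation was weak (Pearson r = 0.095, Spearman rho = 0.034). Both comparisons share the wild-type LSK libraries, and unchanged groups simulated with independent libraries gave r = 0.352 and a covariance of 0.0656 against the observed 0.0363. In 20 such simulations, lists of the real sizes were made, counted over the 10320 genes tested in both comparisons. These sizes were 115 higher and 88 lower genes in Uhrf1-/- and 148 higher and 398 lower genes in LK cells. The simulated lists shared a mean of 15.5 (highest 24) higher genes and 21.8 (highest 29) lower genes. The observed 23 shared higher genes lay within that simulated range and the 39 shared lower genes above it. The 10 genes higher in Uhrf1-/- and lower in LK cells, which go against a move toward LK cells, also lay above their simulated range (highest 7). The simulation treats libraries as independent, whereas the real ones share handling. Its r of 0.352 lay above the observed 0.095, so its ranges cannot decide whether the shared calls exceed what shared controls would give. With no library shared r was 0.102, without wild-type replicate 3 it was 0.366 and without wild-type replicate 2 it was 0.034. Part of the shared calls may come from the shared controls, and how much stays open.

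**Figure D4:**
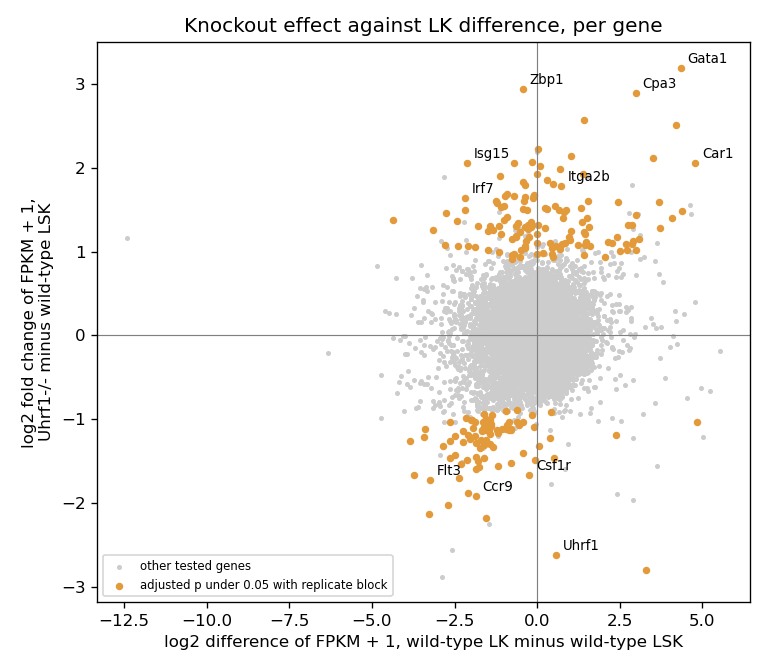
Log2 fold change of FPKM + 1 between Uhrf1-/- and wild-type LSK cells (y axis) against the log2 difference between the LK library and wild-type LSK cells (x axis); each point is a gene, orange where the blocked adjusted p was under 0.05. Gata1 (3.19) and Car1 (2.06) lie at the upper right, Isg15 (2.06) and Irf7 (1.64) at the upper left, and the correlation over all genes is 0.095.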

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

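The alternatives on scaled counts, the block without a pair, the block with median-of-ratios scaling and the correlation with no shared library were chosen after seeing the data. The cause of the changes was not tested unless one is named. Of the genotype calls without the block (12 higher, 6 lower), 0 and 0 were left with no filter, where 16724 genes were tested and 967 had an unadjusted limma p under 0.05. Lower calls were 2 at a minimum of 5 FPKM, which drops low genes, and 1 with plain empirical Bayes. With the replicate block, which removes the spread shared within pairs, there were 131 and 88. Scaled counts gave 7 higher, and 92 and 49 with the block. The block with median-of-ratios scaling gave 117 and 68. Leaving out 1 library gave 0 to 3 higher and 0 to 1 lower calls (0 without wild-type replicate 1 or 2). In the blocked fit, leaving out 1 pair gave 13 to 338 higher and 8 to 318 lower calls, the lowest without pair 2, the highest without pair 1, and 117 and 84 without pair 3. All 18 calls kept their sign in every setting in which they were tested. The blocked fit over all pairs could not change a sign, as its fold changes equal those without the block. Uhrf1 kept a log2 fold change of -2.92 to -2.36 and did not pass with no filter (-2.62, adjusted p = 0.129), without a wild-type replicate (lowest -2.77) or without Uhrf1-/- replicate 2 (-2.42). The lists higher in Uhrf1-/- cells (4) and lower (1) fell to 0 and 0 with an estimated correlation, where camera adjusted p-values ran from 0.060 to 0.448. With the block as well, these were 0.414 for the interferon, megakaryocyte, lymphoid and mast cell lists and 0.675 for the erythroid list. Leaving out 1 library gave 1 to 4 lower lists, with 4 without wild-type replicate 3, and the same range held in the blocked fit. The germline list went from lower (adjusted p = 0.970) to higher (0.017) with no filter, where 23 of its members were tested in place of 6. Among 89 named genes and 20 lists, no called one changed sign, and 12 genes and 11 lists with no call did so in some setting; counting these as unchanged was decided after the counts were seen. The block changed no other list call; 23 named genes passed only with it. camera has no empirical Bayes step, so plain empirical Bayes gave the lists no value, and the 5 FPKM minimum was run on the gene counts only. In LK against LSK cells, the pooled calls were 161 higher at a pseudocount of 0.1 and 222 lower with no filter, against 250 and 399. Without a wild-type replicate they ran from 187 to 425 higher and 284 to 610 lower. Genes beyond the range by at least 2 were 322 above and 594 below at a pseudocount of 0.1, against 182 and 303, and 258 to 459 below without a replicate. The correlation of 0.095 became 0.135 at a pseudocount of 0.1 and 0.034 to 0.366 without a replicate, the highest without wild-type replicate 3. Read depth was not varied, and genes under 1 FPKM, where depth limits these data most, were tested only with no filter.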

Other observations

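Of the tests here, those of single pairs, of macrophages and of LK cells were chosen after the results were seen, while the bounds for the FPKM length term, the other splits and the X chromosome were set before their own values were seen, though after the gene and list results on FPKM, and the scaled counts were an alternative chosen after the data were examined. The genes in the next sentences were picked after their values were seen, lie outside the fixed lists and stand for no group. Isg20 was 27.0 FPKM in wild-type and 90.9 FPKM in Uhrf1-/- cells in the mean, Ifi27 88.7 and 264.7, Oas1g 3.25 and 12.5, and Xaf1 10.9 and 29.1. Apoe, which lies beside Apoc1 on chromosome 7, was 547.8 and 2075 FPKM. Dusp5 was 34.5 and 12.9 FPKM, Dusp6 18.8 and 7.40, Spry1 13.03 and 4.65, Ccl3 46.2 and 9.84, and Cd7 5.79 and 0.839. All of these passed limma with the replicate block, where the simulated share of false calls, with the pairing assumed, was 9.31%. None passed without the block (adjusted p from 0.058 to 0.949).

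Interferon-stimulated genes were higher as a group in Uhrf1-/- LSK cells, though the camera call was lost with an estimated correlation (adjusted p = 0.060). Of 31 tested members, 1 was called among all genes without the block and 13 with it. If handling of a single replicate pair were the source of the rise, a pair would show no difference, and the lowest of the 3 pair medians was 0.790 on the log2 scale. Macrophages, which a lineage gate removes where its panel covers them, would raise C1q transcripts in the knockout sorts, and the C1q sum was over 1.5 times lower in Uhrf1-/- cells in both pairs 1 and 2 (146.5 against 33.5 and 70.1 against 35.4 FPKM, 2 of 2 pairs). In pair 3 the sum was 1.89 times higher in Uhrf1-/- cells at levels near 0 (1.12 against 2.12 FPKM) and the macrophage list had a median of 0.50, so macrophages stay open there. The per-library length term of the FPKM values is absent from the scaled counts, where the list median was 1.34, and the genotype stays among the open explanations, as untested.

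Some megakaryocyte and erythroid genes were higher in Uhrf1-/- LSK cells, and LK cells carried through the Sca-1 gate could be a source. Of 24 tested erythroid genes, 15 had a positive and 9 a negative log2 fold change, and of 11 megakaryocyte genes 8 and 3. Both camera calls were lost with an estimated correlation (adjusted p = 0.448 for the erythroid and 0.066 for the megakaryocyte list). Over the 11 tested megakaryocyte genes, the LK library differed from wild-type LSK cells by a median of -0.17 on the log2 scale, against 1.07 for the Uhrf1-/- cells. For the erythroid genes, Gata1 alone would need between 37.9% and 48.9% LK cells of the measured profile. The median over 14 other erythroid genes abundant in LK cells implied at most 3.73%, but these genes were split. Their mean implied shares ran from -4.98% for Tfrc to 17.65% for Hemgn. The LK profile comes from 1 library, and subsets of LK cells with another profile were not measured, so carried-over LK cells stay open, as does the genotype, untested. Ly6a, which encodes Sca-1, was 84.6, 96.4 and 36.9 FPKM in the Uhrf1-/- libraries and 56.8, 34.3 and 26.4 FPKM in the wild-type ones. Its log2 fold change was 0.83 and did not pass (blocked limma adjusted p = 0.128). These RNA values do not show which cells the Sca-1 gate took in.

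Lymphoid genes and the myeloid genes Csf1r and S100a8 were lower in Uhrf1-/- LSK cells, and macrophages in the wild-type sorts were weighed as the whole cause. The lymphoid camera call was lost with an estimated correlation (adjusted p = 0.060). Without the block 2 of the 15 lymphoid genes were called, and S100a8 passed only with it. In pair 3, where each C1q gene was below 2 FPKM in both libraries, the 15 tested lymphoid genes had a median log2 difference of -1.22, which argues against macrophages as the whole cause for that list. Csf1r and S100a8 had log2 differences of -1.64 and -2.74 in pair 3, and macrophages with the C1q share of pair 1 or 2 would need a C1q sum of at least 20.9 FPKM in wild-type replicate 3 to make these, where it was 1.12, which argues against them as the whole cause for these genes as well. The macrophage list had medians of -1.73, -0.87 and 0.50 in the 3 pairs, so a part played by macrophages in pairs 1 and 2 stays open for all of these genes. The genotype stays among the open explanations, as untested. Each library pools sorted cells, so a changed mix of cells within the LSK gate cannot be told from a change per cell. That limit also holds for the interferon-stimulated, megakaryocyte and erythroid genes above.

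The real split of the 6 LSK libraries called 18 genes, and the highest of the other 9 splits into 3 and 3 called 1, so 1 of the 10 splits gave as many. With the block, the real split called 219 genes and the highest of the other 3 splits that part all pairs called 1, so 1 of the 4 gave as many. With 10 and 4 splits a share under 0.05 cannot be reached. The other splits that part all pairs exchange the genotype within 1 pair.

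Because Uhrf1 maintains DNA methylation, which holds the inactive X chromosome silent in females, it was asked whether the genes that rose in the blocked fit lay more often on the X chromosome. They numbered 5 of 128 with a chromosome, among them Gata1, Rhox5 and Xlr, against 322 of 10466 tested genes (odds ratio 1.29, 95% confidence interval 0.407 to 3.11, Fisher's exact p = 0.600, two-sided). An interval that includes 1 had been set, before the odds ratio was seen, as the outcome against enrichment, which was a poor bound, because this interval also holds an odds ratio of 3.11 and the question stays open at this number of genes.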
